A study of Rattus norvegicus with 4 samples.

How the data were processed

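Total RNA of the rat mammary gland was measured on 4 expression arrays, 1 for each of 4 groups of 5 Lewis rats: parous and age-matched virgin rats without treatment, and parous and age-matched virgin rats after N-methyl-N-nitrosourea (MNU). The groups were taken from the sample titles. The values the authors deposited are positive intensity values on a linear scale, given to 3 significant digits, with blanks where no value is given. No value lay near 0 and the array medians differed by up to 1.33 times, so the deposited intensities showed neither subtraction of background to 0 nor scaling between arrays. The array platform, the image processing, the meaning of a blank and whether the RNA of the 5 animals was pooled are not given in the sources used here. The table held 20500 features. Of these, 12750 carried 1 gene symbol, and 12720 were matched by gene identifier to the current names of the rat assembly GRCr8, which was used for names alone. The 7745 features without a symbol and the 5 with several entered no gene comparison. No column of another sample was present.

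The design asked for quantile normalization if the array medians differed by more than 1.1 times, which they did. The curve of the normalization was estimated on features with a value on all 4 arrays and carried to the others by interpolation. This form was adopted after simulated data, and a first set of results, had been seen: the MNU arrays lack more of their brightest features, and normalization over all values of each array raised the remaining bright genes on them. The median difference of the brightest 5% of genes between the MNU and untreated arrays was 0.27 in virgin and 0.26 in parous glands on the log2 scale with all values, against -0.05 and 0.00 with the form used. Normalized intensities were raised to a floor at the pooled 40th percentile, 176.9 units, and put on the log2 scale. A feature was kept if at least 1 array exceeded the pooled 50th percentile, 215.1 units. This left 11098 features. Each gene was represented by its brightest kept feature, which gave 6180 genes, of which 5580 had a value on all 4 arrays. Blanks were never filled in.

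Parous was compared with virgin within the untreated and within the MNU arrays, and MNU with untreated within virgin and within parous arrays. Because each group had 1 array, single comparisons gave log2 differences and counts of genes at least 2-fold different, with no p-value. Both parity pairs, which share no array, were then combined in an additive model of parity and MNU with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without a trend and Benjamini-Hochberg adjustment at 0.05. That model leaves 1 residual degree of freedom per gene. It borrowed 10.9 prior degrees of freedom across genes, with a prior SD of 0.114 and a median standard error of 0.112 on the log2 scale. Any difference between the pairs enters its error, and its p-values measure the spread among these 4 arrays alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

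For 29 gene lists covering cell types and processes of the gland, the median log2 difference of the measured members was ranked among 10000 random lists of equal size matched on 10 bins of mean expression. Lists with fewer than 5 measured members were reported by member only. A list was read as standing apart below percentile 0.5 or above 99.5. The genes named in each comparison were the 8 with the largest positive and the 8 with the largest negative difference of at least 2-fold, the genes at least 2-fold different in both pairs, up to 4 members per list with the largest difference, and 19 genes of milk secretion, hormone action, proliferation and DNA damage.

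The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The bounds on percentiles were set later, before any list median was computed. The form of quantile normalization, the subtraction of the 1st percentile as background, the removal of a local median over 15 by 15 positions and the list medians for the difference of the MNU effects were added after values had been seen. Positions and neighbours on the array were derived from the feature numbers, read as 105 rows of 215 features. That layout is an assumption, since the platform is not given. The other alternatives covered scaling between arrays, the floor, the filter, the handling of several features per gene, the fold threshold and the settings of limma.

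The procedure was tested on simulated data with 200 changed genes and a noise SD of 0.11 on the log2 scale. The changed genes were drawn only from genes with values on all 4 arrays that lay well above the floor. The recovery rates therefore do not cover dim genes. Counting genes 2-fold different in both parity pairs recovered 0% of genes simulated at 1.5-fold, 22% at 2-fold, 100% at 3-fold and 98% at 4-fold. It called 0 of 5934 unchanged genes. With noise this small an unchanged gene could hardly reach 2-fold in both pairs, so this 0 says little about false calls in the real data. The limma model recovered 88% at 1.5-fold and 100% at each larger size. Of its 218 calls, 24 were unchanged genes, or 11.0%, which is above the nominal 5%. The simulated noise was drawn independently for each feature, without trends over the array or differences among animals. False calls in the real data may therefore be more frequent than in these simulated data.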

Results

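The data describe the mammary gland of Lewis rats in 4 states, each measured on 1 array. Parous rats gave birth at 87 days of age, nursed for 21 days and then had 28 days of involution, the regression of the gland once the litter is removed. They were examined at 136 days beside virgin rats of equal age. Another 5 parous and 5 virgin rats were given MNU at 50 mg/kg, an alkylating carcinogen that induces mammary tumours in rats, and were examined 3 weeks later, at 157 days. MNU and the additional 3 weeks of age cannot be told apart. Litters were removed at 108 days in both parous groups, so for parous rats these weeks were also additional time after litter removal. Virgin rats have no such difference. Median intensities were 226 units for parous, 238 for virgin, 179 for parous with MNU and 221 for virgin with MNU. These arrays had 421, 390, 795 and 666 blanks. The MNU arrays held more blanks than the untreated arrays, so a technical difference cannot be told apart from MNU and age either. With 1 array per group a difference within a single pair has no replicate check, and the number of arrays limits the precision.

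The comparison of parous with virgin glands at 136 days asked what a completed cycle of pregnancy, lactation and involution left in gland expression. Milk genes differed most. Csn1s2a, which encodes an alpha-S2 casein, was 14.5-fold higher in the parous gland at 11348 against 780 units, a log2 difference of 3.86. Wap, the gene of whey acidic protein, was 4.04-fold higher with a log2 difference of 2.01, and Spp1, which encodes osteopontin, a phosphoprotein found in milk, was higher by 1.25. All 7 measured members of the milk list lay above 0. Their median of 0.64 exceeded all 10000 random lists.

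Genes of immune cells were also among those highest in the untreated parous gland. Jchain, the joining chain of secreted IgA and IgM made by plasma cells, was 4.47-fold higher with a log2 difference of 2.16. Mmp12, the metalloelastase of macrophages, was higher by 1.33, Gpnmb, a membrane glycoprotein abundant in macrophages, by 1.18, and Gzma, a protease of cytotoxic lymphocytes, by 1.15. Broader immune lists did not stand apart, with medians of 0.07 for 7 T cell genes and 0.03 for 10 myeloid genes. Lower in the parous gland were Reg3a at -1.55 and Reg3b at -1.05, secreted lectins with antibacterial activity. Areg, which encodes amphiregulin, a ligand of the EGF receptor active in duct growth, stood at -1.18. Padi2, an enzyme that converts arginine to citrulline in proteins, stood at -1.20 and Msln, the gene of mesothelin, at -1.14. Myl11, a myosin light chain of fast muscle, stood at -1.01, though its other kept feature stood at -0.05, and the median of 9 skeletal muscle genes was -0.16, at percentile 0.71.

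Of 5987 genes with values on both untreated arrays, 19 were at least 2-fold higher and 8 at least 2-fold lower in the parous gland, 27 in all. The robust SD of all differences was 0.156 on the log2 scale. Among 5 measured genes reported lower after parity in rodents the median was -0.22, at percentile 1.26, with Areg at -1.18, Ptn at -0.23, Igf1 at -0.22, Lep at -0.09 and Ghr at 0.12. Of the genes reported higher, 4 were measured: Wap at 2.01, Spp1 at 1.25, Cp at 0.37 and Tgfb3 at 0.25. Csn2, the gene of beta-casein, read 1210 units and Glycam1 1280 units in the virgin gland, and both were blank on both parous arrays, while Csn1s1, Csn3 and Lalba were blank on all 4. With the 1st percentile subtracted as background the count of 27 became 43. Of 4 called genes with another kept feature 3 had the same sign in it and 1, Mmp12, at least 1.5-fold. Over 795 genes with 2 features the differences correlated with r = 0.228. That r was 0.306 for parity with MNU, 0.197 for MNU in virgin glands and 0.0741 for MNU in parous glands.

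After MNU, the same comparison asked whether parous and virgin glands differed 3 weeks after the carcinogen. Cell cycle genes were lower in the parous gland, where they were near the untreated level and the virgin MNU array stood out. Cdk1 read 372.1 units on the parous MNU array, 380.5 and 353.3 on the untreated parous and virgin arrays, and 850.9 on the virgin MNU array. Pclaf, a factor bound to PCNA in DNA replication, differed by -1.47, Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, by -1.21, and Cdk1, the kinase that starts mitosis, by -1.19. Mki67, the proliferation marker Ki-67, differed by -0.93. The median of 17 measured cell cycle genes was -0.29, below all 10000 random lists, and 11 of them lay below 0. Fatty acid synthesis genes showed a median of -0.50, also below all random lists, with 7 of 8 members below 0, among them Scd2, a stearoyl-CoA desaturase, at -1.12 and Elovl6, a fatty acid elongase, at -1.07.

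Milk genes were again higher in the parous gland after MNU, with a median of 0.57 over 6 members, above all 10000 random lists, and of 0.18 as deposited. Csn1s2a was higher by 1.86, Wap by 0.95, Xdh by 0.61 and Muc1 by 0.53. Jchain was higher by 1.84 and Dbp, a transcription factor of the circadian clock, by 1.6. Genes of the acute phase and innate defence had a median of 0.25, at percentile 99.96, with S100a9 at 0.77, C3 at 0.40 and Lcn2 at 0.40. As deposited, without scaling, that median was -0.12, where the median of all genes was -0.36. Interferon response genes had a median of -0.26, at percentile 0.32, with Psmb9 at -0.46 and Irf7 at -0.44. Magee1 was at least 4.95-fold higher on the parous MNU array, since it lay at the floor on the other 3 arrays. Uhrf1, a partner of DNA methylation in replicating cells, lay at the floor there, so that its difference of -1.14 is a bound.

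The interferon median no longer stood apart without genes that another list also holds, Psmb9 among them, the acute phase median with the strict filter, and the fatty acid synthesis median without a filter. In total 9 genes were at least 2-fold higher and 15 at least 2-fold lower, 24 of 5679, and the robust SD was 0.2. As deposited the count was 67, of which 62 were lower, alongside the shift of all genes by -0.36; it was 15 with the strict filter and 45 with background subtracted. In the limma model over both pairs, 0 of 17 cell cycle genes, 0 of 7 fatty acid synthesis genes, 0 of 8 interferon genes and 0 of 8 acute phase genes passed for parity. Adjusted over the list alone, 1, 1, 2 and 4 of them passed. The model averages both pairs and takes their disagreement as error. These counts therefore do not test a difference confined to the MNU pair. At an unadjusted p under 0.05, limma counted 547 genes for parity.

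Both parity pairs together hold 9 genes at least 2-fold different in the same direction, out of 5580. Csn1s2a had a mean difference of 2.86 ± 0.31 (SE, 2 arrays per parity state, limma adjusted p = 5.36e-04), and Jchain of 2.0 ± 0.12 (adjusted p = 6.35e-06). Bcar3, an adaptor protein linked to resistance of breast cancer cells to antioestrogens, was higher by 1.12 and 1.45, and Hepacam2, a cell adhesion protein, by 1.12 and 1.37. Gzma and Gpnmb completed the 6 higher genes, with adjusted p = 4.28e-04 each. Padi2 had a mean of -1.23 ± 0.11 (adjusted p = 2.38e-04), Msln of -1.14 ± 0.11 (adjusted p = 2.76e-04) and Reg3a of -1.28 ± 0.14 (adjusted p = 4.97e-04). No gene was at least 2-fold different in opposite directions in the parity pairs. As deposited 3 genes were higher and 4 lower in both pairs, and 6 of the 9 stayed 2-fold different in both.

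**Figure D1:**
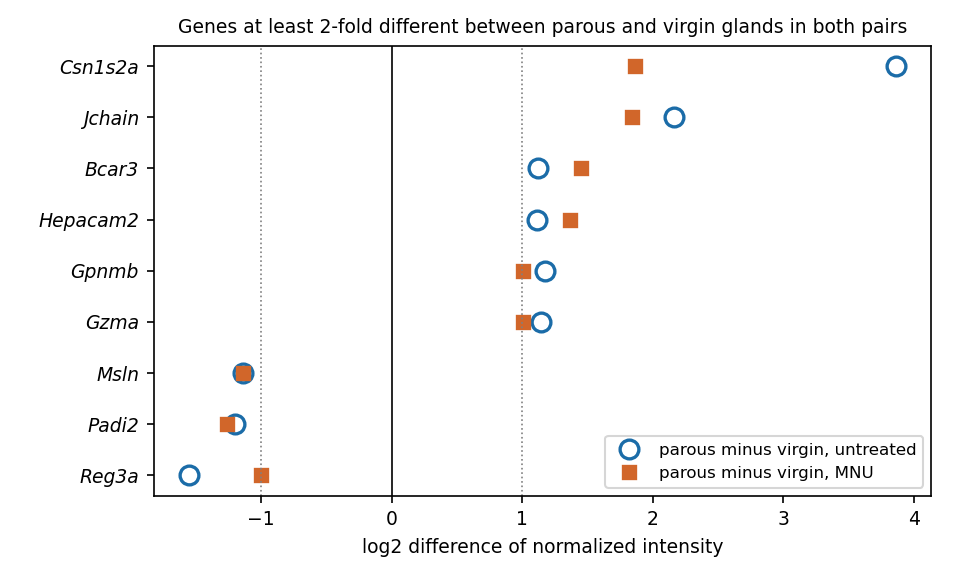
Log2 difference of normalized intensity, parous minus virgin, for each of the 9 genes at least 2-fold different in both pairs; open circles show the untreated pair, squares the MNU pair, each from 1 array per group, and dotted lines mark 2-fold. Csn1s2a differed by 3.86 without and 1.86 with MNU, and Reg3a by -1.55 and -1.0.

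With limma, 42 genes rose and 26 fell with parity over the 2 pairs, 68 of 5580, with mean differences from 0.52 upward in size. As deposited, without scaling, 13 rose and 35 fell. Milk genes rose: 4 of 6 members with complete values passed, and 4 adjusted over the list alone, namely Csn1s2a, Wap at 1.48 ± 0.19, Muc1 at 0.59 ± 0.11 and Xdh at 0.58 ± 0.11. Metallothioneins, which bind zinc and copper, rose as well, Mt2A by 0.98 ± 0.12 (adjusted p = 0.00123) and Mt1 by 0.64 ± 0.13 (adjusted p = 0.0305). Igf2, a fetal growth factor, fell by 0.84 (adjusted p = 0.00672), and Ltbp2, a matrix protein of the TGF-beta binding family, fell by 0.82 (adjusted p = 0.00531). Muscle genes Myl11 and Actn3 fell by 0.79 and 0.59 (adjusted p = 0.00931 and 0.0217), but the other kept feature of Myl11 differed by -0.05 and -0.18. The luminal list had medians of 0.14 untreated and 0.18 with MNU, at percentiles 99.31 and 99.42, neither standing apart. Within it Muc1 rose and Krt7 fell by 0.56 (adjusted p = 0.0305), 2 of 10 members. Adjusted over the list alone, 3 members passed. As deposited the luminal median with MNU was -0.19, with all genes at -0.36.

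Across the genes of both pairs the parity differences correlated with r = 0.309 and rho = 0.180; genes are not independent replicates. The call of 68 genes depended on the filter, with 0 calls without a filter, where 2454 genes were equal on all arrays and limma's prior fell to 0.383 degrees of freedom, and 158 with the strict filter; it was 45 with the mean of a gene's features and 43 with the local median removed. A crossed split, parous and virgin MNU against virgin and parous MNU, gave 0 calls in limma and 127 genes at an unadjusted p under 0.05. Of other genes named in advance, Tgfb3 read 0.25 and 0.74 (adjusted p = 0.117), Mgmt, which repairs alkylated guanine, -0.35 and -0.30 (adjusted p = 0.257), and Prlr 0.08 and 0.09. Esr1, Pgr and Top2a did not pass the intensity filter.

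MNU and the 3 weeks of age were then compared with the untreated state in virgin glands, which asked how the susceptible gland differed after the carcinogen. Genes of fatty acid synthesis were highest. Elovl6 was 3.69-fold higher with a log2 difference of 1.88, Thrsp, a regulator of lipogenesis, was 3.61-fold higher with 1.85, and Pc, pyruvate carboxylase, was higher by 1.62. Acly, which makes cytosolic acetyl-CoA, was higher by 1.16. All 7 measured members lay above 0, and their median of 1.16 exceeded all 10000 random lists. Adipocyte genes had a median of 0.21, at percentile 99.81, led by Gpd1 at 1.26 and the glucose transporter gene Slc2a4 at 0.79.

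Cell cycle genes were higher on the virgin MNU array as a group. Cdk1 was higher by 1.27, Stmn1, a microtubule regulator of dividing cells, by 1.23, Ube2c by 1.20 and Mki67 by 1.18. Of 18 measured members 16 lay above 0, and the median of 0.44 exceeded all 10000 random lists. Genes of mitochondrial oxidative phosphorylation had a median of 0.23, at percentile 99.92, with Atp5mc3 at 0.60 and Cox4i1 at 0.48. Csn1s2a was higher by 1.47. Immediate early genes, which respond within minutes to stress and growth signals, were lower in all 12 measured members, with a median of -0.33, below all 10000 random lists. Zfp36 differed by -0.89, Jun by -0.55 and Junb by -0.52. Myeloid genes had a median of -0.21, at percentile 0.27, with Clec10a at -0.33 and Fcgr2b at -0.26. Ccn2, a matrix-associated growth regulator, differed by -1.24 and Nnat, the gene of neuronatin, by -1.23. Gnb5 differed by -1.15, but its other kept feature by 0.34.

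Without a filter the cell cycle median was 0.14 and the fatty acid synthesis median 0.65, both still apart. In virgin glands 17 genes were at least 2-fold higher and 6 at least 2-fold lower, 23 of 5814, with a robust SD of 0.189; the count was 57 with background subtracted, 32 higher and 25 lower, and 23 as deposited, 14 higher and 9 lower. The adipocyte median no longer stood apart without the filter, with the strict filter or with quantile normalization over all values, and the myeloid median did not without the filter, with that normalization or with the local median removed. Genes of the DNA damage response had a median of 0.08, at percentile 88.5, with Cdkn1a at 0.14, Mdm2 at 0.14 and Mgmt at -0.03. Pcna differed by 0.42.

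In parous glands the same comparison asked the same of the gland with an earlier pregnancy. Fatty acid synthesis genes again stood apart, with a median of 0.49 above all 10000 random lists and 7 of 8 members above 0; as deposited it was 0.06, where all genes shifted by -0.40. Thrsp was 2.02-fold higher with 1.01, Pc was higher by 0.77 and Elovl6 by 0.57. Cell cycle genes had a median of 0.00, at percentile 50.5, with 8 members above and 8 below 0, Cdk1 at -0.03 and Mki67 at -0.12. Immediate early genes had a median of -0.19, at percentile 0.28, with Atf3 at -0.68 and Jun at -0.42. That median did not stand apart without the filter or with the mean of a gene's features. Cldn7, a claudin of epithelial tight junctions, differed by -1.31, Bst2, an antiviral membrane protein, by -1.11, and Kif3b, a kinesin, by -1.05.

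Only 2 genes, Magee1 and Thrsp, were at least 2-fold higher and 3 at least 2-fold lower in parous glands, 5 of 5785, with a robust SD of 0.194. As deposited the count was 44, of which 43 were lower, with all genes shifted by -0.40. It was 2 with the strict filter, 13 with background subtracted, 8 with each feature counted on its own and 3 with the local median removed.

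Thrsp was the single gene at least 2-fold higher with MNU and age in both parity states. With centring or the local median removed no gene was, as Thrsp in parous glands stood at 0.88 and 0.94, and as deposited Thrsp stood at 0.50 there and 1 gene was 2-fold lower in both. With limma, 9 genes rose and 5 fell over the 2 pairs, 14 of 5580. Thrsp had a mean of 1.43 ± 0.16 (SE, 2 arrays per MNU state, adjusted p = 0.00809), Pc of 1.20 ± 0.16 (adjusted p = 0.0144), Elovl6 of 1.23 ± 0.22 (adjusted p = 0.0481) and Gpd1, which makes the glycerol backbone of fat, of 0.92 ± 0.15 (adjusted p = 0.032). Mtarc1 and Pxmp2, each chosen after its values were seen, rose by 0.88 ± 0.11 and 0.90 ± 0.11, with adjusted p = 0.00809 each. Nnat fell by 0.92 (adjusted p = 0.0285). Of the fatty acid synthesis genes 3 of 7 passed and 5 adjusted over the list alone, and of the cell cycle genes 0 of 17 and 2. Adipocyte genes passed in 1 of 9 and 2 cases, oxidative phosphorylation genes in 0 of 13 and 3, immediate early genes in 0 of 12 and 4, and myeloid genes in 0 of 9 and 1.

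The limma count for MNU and age was less stable than that for parity. It ranged from 0 without a filter, with each feature on its own or with the local median removed to 135 with the strict filter, and as deposited 70 genes passed, 66 of them lower. At an unadjusted p under 0.05 the main setting counted 708 genes, and the settings with 0 calls 828, 1278 and 487. Over the 4 comparisons 14 of 98 list medians stood apart, against 0.98 for random lists. The value of 0.98 takes the members of a list as unrelated genes. Members of a list may vary together, some lists share genes, and the comparisons share arrays. The excess over 0.98 therefore does not measure an effect of parity or of MNU and age. The differences of the virgin and the parous pair correlated across genes with r = 0.288 and rho = 0.273. A technical difference shared by the MNU arrays could also contribute to that correlation.

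**Figure D2:**
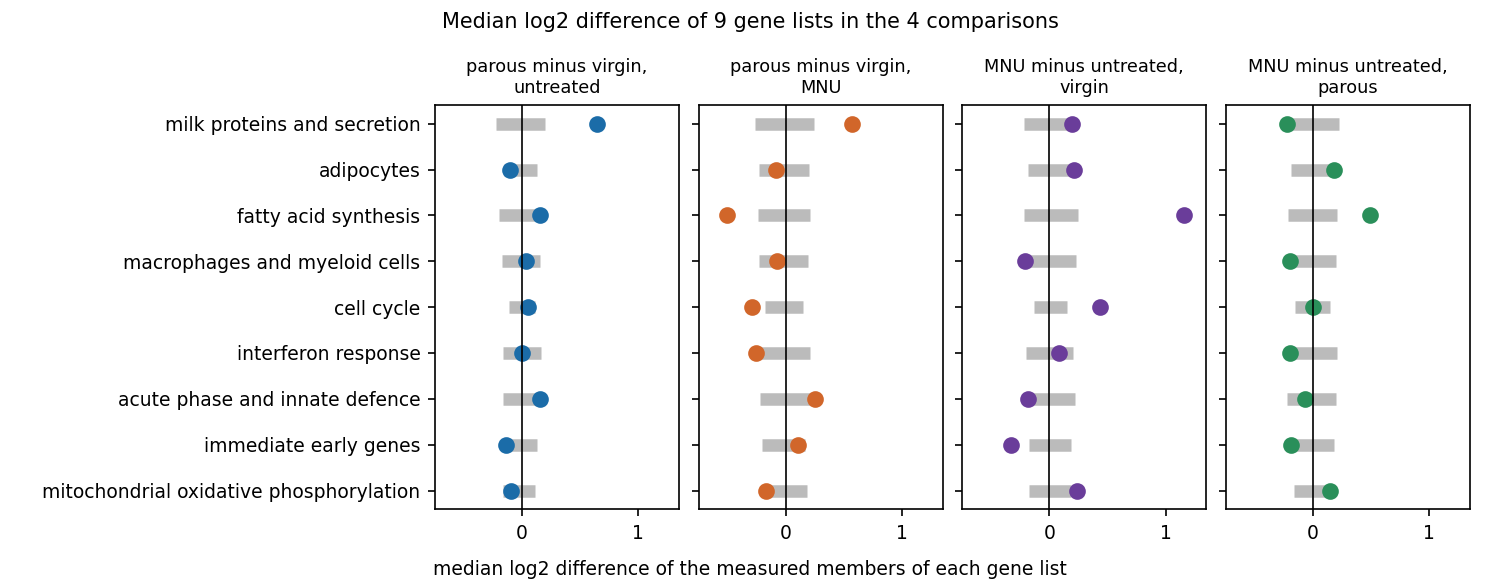
Median log2 difference of the measured members of the 9 gene lists that stood apart in at least 1 comparison, with 1 panel per comparison and 1 array per group; grey bars span the central 99% of 10000 random lists matched on expression. Fatty acid synthesis genes lay at 1.16 in virgin and 0.49 in parous glands after MNU, and milk genes at 0.64 and 0.57 in the parity pairs; adipocyte and oxidative phosphorylation genes in parous glands and acute phase genes in the MNU parity pair lay below 0 as deposited.

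The difference between the MNU effects of parous and virgin glands asked whether the difference with MNU and age depended on a completed pregnancy. Only the parous pair also differs in time after litter removal. This contrast cannot tell that time apart from an altered response to the carcinogen. Csn1s2a stood at -2.0, parous minus virgin, and Magee1 at 2.31, which is no bound because Magee1 lay at the floor on both virgin arrays. Genes of proliferation and lipogenesis were among the others, with Ube2c at -1.41, Elovl6 at -1.31, Cdk1 at -1.30 and Mki67 at -1.30. Fatty acid synthesis genes had a median difference of -0.85, below all 10000 random lists, and cell cycle genes of -0.22, at percentile 0.06. For both lists this is no separate observation. It rests on the same virgin MNU array as their differences for MNU in virgin glands and for parity after MNU. Of 5580 genes 3 differed by at least 2-fold upward, among them Dbp at 1.02, and 21 downward, 24 in all, of which 4 belonged to the cell cycle list, 2 to the milk list and 1 to the fatty acid synthesis list, with a robust SD of 0.236. No gene was at least 2-fold higher in one state and at least 2-fold lower in the other. The crossed split described above is this same contrast halved and with its sign turned, so limma called 0 genes for it, with 127 at an unadjusted p under 0.05, in a model whose error includes any effect of parity. The count was 67 as deposited, 1 upward and 66 downward, 41 with each feature on its own, 12 and 29, and 67 with background subtracted, 23 and 44, and the cell cycle median did not stand apart with median centring, as deposited or without the filter.

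**Figure D3:**
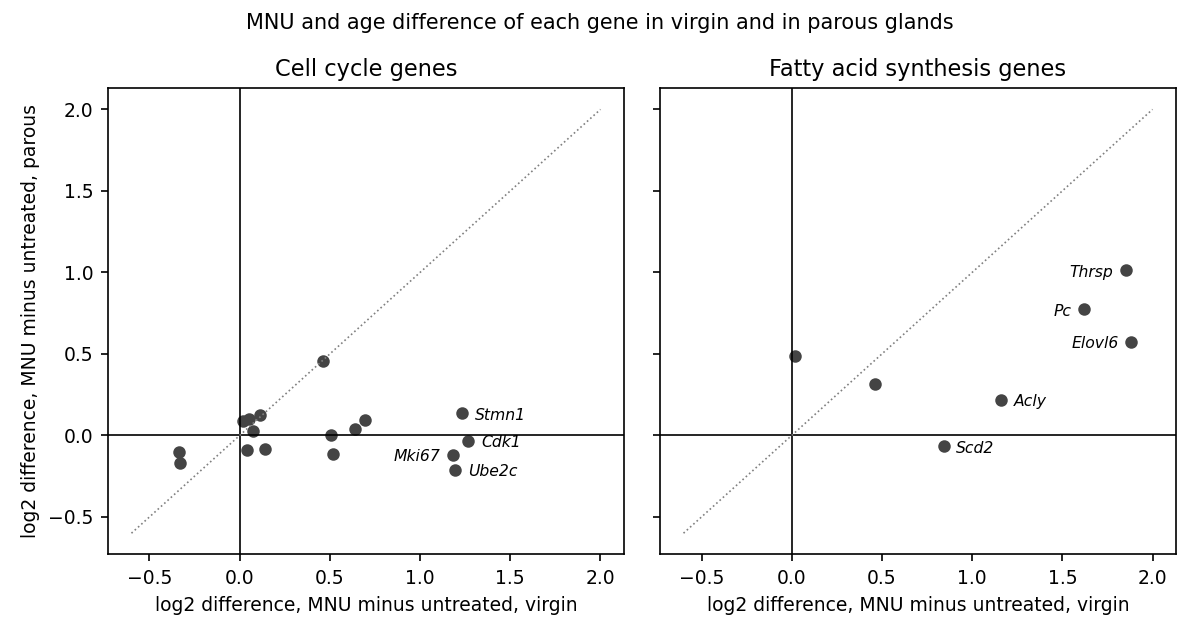
Each point is 1 gene of the cell cycle list, left, or the fatty acid synthesis list, right, with its log2 difference between MNU and untreated glands in virgin rats on the horizontal axis and in parous rats on the vertical axis, from 1 array per group; the dotted line marks equal differences. Cdk1, Stmn1, Ube2c and Mki67 lie at 1.18 to 1.27 in virgin and at -0.21 to 0.14 in parous glands.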

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

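The tests of a local trend, lymph node tissue, scaling and other cell types reported in this part were chosen before their results were seen, while the bounds that selected the list medians of the next paragraph, and the removal of the local median itself, were chosen after the data had been seen.

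Milk genes drew attention because their medians lay on opposite sides of 0 after MNU, at 0.20 in virgin glands with 6 of 8 members above 0, and at -0.23 in parous glands with 7 of 7 below 0. Neither median stood apart, at percentiles 98.8 and 0.72, and the measured members differed, since Csn2 and Glycam1 had values in virgin glands alone and Spp1 in parous glands alone. In parous glands the additional time after litter removal cannot be told apart from MNU and age. Fatty acid synthesis genes had a median of 0.15 for parity without treatment and -0.50 with MNU, and immediate early genes of -0.14 and 0.11. The difference between the pairs, which is the same contrast for parity and for MNU, ranked at percentile 4.32 among random lists for milk genes and 99.1 for immediate early genes, neither apart, and at 0 for fatty acid synthesis genes. For single genes limma called 0 of 5580 on this contrast, with 127 at an unadjusted p under 0.05, and its error there includes any effect of parity. Among 3961 kept features without 1 gene symbol, which enter no comparison of genes, 3 were at least 2-fold different in the same direction in both parity pairs, 2 higher and 1 lower, and 0 in opposite directions.

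The 9 genes at least 2-fold different in both parity pairs, led by Csn1s2a and Jchain, were weighed against a pair of technical explanations. If a broad trend across the array surface made the differences, removing the local median would take much of them away. Instead 9 of 9 genes kept at least 0.8 of both, and 7 of them stayed at least 2-fold different in both pairs. As deposited, where all genes of the MNU pair shifted by -0.36, 6 stayed so and 3 kept 0.8 of both. The removal was partial. Differences of neighbouring features in a row correlated with r = 0.300 untreated and 0.201 with MNU before it, and 0.193 and 0.114 after it. Finer trends therefore stay open. Lymph node tissue on both parous arrays would bring Jchain and Gzma with other lymphocyte genes, and the higher of the T cell medians was 0.0938. That median decides little, because Cd3e, Cd8a, Lck and Zap70 lay near the floor of 176.9 units, where a rise shows only weakly. Of the brighter T cell genes, Cd3d differed by 0.07 untreated and 0.25 with MNU, and Cd8b by -0.18 and 0.09. Tissue rich in T cells therefore stays open. Follicles of B cells stay open as well, since fewer than 5 B cell genes were measured. Cxcl13, a chemokine of such follicles, was higher by 1.02 in the MNU pair. A higher share of luminal cells in the parous samples was not tested for the 9 genes and stays open. The luminal medians were 0.14 untreated and 0.18 with MNU, at percentiles 99.31 and 99.42, neither standing apart. Parity may explain the genes other than Jchain and Gzma, as a hypothesis. Differences among the 5 animals of a group and in how their tissue was sampled were not tested.

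The higher cell cycle genes of the virgin MNU array, with a median of 0.44, were weighed against 4 explanations. With the local median removed the median was 0.43, which argues against a broad surface trend. Neighbouring features in a row still correlated after that removal, with r = 0.158 against 0.331 before, so finer trends stay open. With centring, cyclic loess and as deposited the median was 0.45, 0.44 and 0.31. It lay above 0 without any scaling although all genes then shifted by -0.10, which argues against scaling as the whole cause. The lowest value relative to all genes, 0.41, decides little because a constant shift cancels from it. More epithelial cells would raise luminal and basal genes, but the higher of their medians was 0.0478. More immune cells would raise B cell, T cell and myeloid genes, and the higher of the T cell and myeloid medians was -0.10. Fewer than 5 B cell genes were measured, so a higher share of B cells stays open. Several T cell genes also lay near the floor. Proliferation in the virgin gland after MNU may explain the pattern, and the additional 3 weeks of age and differences among animals remain open and were not tested.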

How the results depend on the processing

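The subtraction of background, quantile normalization over all values, the local median and the list medians for the difference of MNU effects were added after the data had been seen. Counts stayed within 1.5 times except as follows, and the cause was not tested unless given. Quantile normalization, first set as an alternative, is the main setting itself. No paired analysis was possible because each group had 1 array and no label links animals.

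As deposited, where all genes shifted by -0.08, -0.36, -0.10 and -0.40 in the order of comparisons, the parity count with MNU was 67, MNU in parous glands 44, the difference of MNU effects 67, the limma count for MNU and age 70 and the lists standing apart 24 instead of 14; the acute phase median in the MNU parity pair was -0.12, and limma's parity count was 48 with 13 higher and 35 lower, and 0 genes were 2-fold higher and 1 lower in both MNU pairs. That shift is the unscaled difference in array brightness. Centring gave 22 lists and 0 genes 2-fold in both MNU pairs, and cyclic loess 25 limma genes for MNU and age, 11 higher and 14 lower.

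Without a filter limma called 0 genes for parity and 0 for MNU and age, against 733 and 828 at an unadjusted p under 0.05; 2454 of 8841 genes were then equal on all arrays and the prior fell to 0.383 degrees of freedom. The strict filter gave 158 and 135, with a prior of 48.8 degrees of freedom, and 2-fold counts of 15 for parity with MNU and 2 for MNU in parous glands, on fewer genes. Gnb5 in virgin MNU glands was 0.34 with the strict filter and 0.34 with the mean of its features, since both settings use features with a value on all 4 arrays and the main feature of Gnb5 is blank on the parous MNU array. The mean of features gave limma counts of 45 and 3. With each feature on its own, MNU in virgin glands gave 35, in parous glands 8, the difference of effects 41 and limma for MNU and age 0, with 1278 unadjusted.

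Subtracting the 1st percentile widens every fold by construction: 43 for parity untreated, 45 with MNU, 57 for MNU in virgin and 13 in parous glands, and 67 for the difference of effects. Quantile normalization over all values gave 85 limma genes for MNU and age. With the local median removed, MNU in parous glands gave 3, both MNU pairs 0, limma 43 for parity and 0 for MNU and age, with 487 unadjusted.

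By construction, thresholds of 1.5-fold and 3-fold moved the counts to 100 and 3 for parity untreated, 130 and 4 with MNU, 133 and 3 for MNU in virgin glands, 57 and 1 in parous glands, 33 and 2 for both parity pairs, 10 and 0 for both MNU pairs, and 181, with 68 upward and 113 downward, and 2 for the difference of effects. For MNU and age, limma counted 55 at an adjusted p of 0.1 and 3 with robust variances.

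Of medians that stood apart, those of the cell cycle and fatty acid synthesis fell in size without a filter, to -0.12 and -0.15 for parity with MNU and to -0.10 and -0.50 for the difference of effects, and immediate early genes to -0.18 in virgin and -0.07 in parous glands with quantile normalization over all values. Of 1335 list medians under alternatives 1101 moved little, 233 moved further and 1 reversed; of 4952 values of named genes 4603, 347 and 2. Signal over background limits genes near the floor of 176.9 units, where a difference is a bound if 1 of its arrays lies at the floor and carries no information if both do, and Esr1, Pgr and Top2a lay under the filter.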

Other observations

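All 3 tests on blank values in this part were chosen only after the blanks had been seen; the list medians were set out before.

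Cell types and processes not described above showed no median outside the central 99% of random lists. In the order parity untreated, parity with MNU, MNU in virgin and MNU in parous glands, basal and myoepithelial genes had medians of 0.01, 0.05, 0.05 and 0.01, fibroblast genes 0.06, -0.11, -0.05 and -0.15, endothelial genes -0.11, -0.01, -0.17 and 0.07, and mast cell genes -0.09, -0.12, -0.09 and 0.01. Genes of antigen presentation by MHC class II had medians of -0.12, -0.08, 0.09 and 0.06, peripheral nerve genes -0.07, 0.13, -0.05 and 0.15, heat shock genes -0.05, -0.11, -0.03 and -0.09, and ribosomal protein genes -0.08, -0.01, 0.04 and 0.06.

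Hormone axis genes had medians of -0.14, 0.05, 0.05 and 0.03, TGF-beta genes -0.01, 0.11, -0.14 and 0.06, and genes of xenobiotic metabolism 0.02, 0.09, 0.09 and 0.03. Genes of the p53 and DNA damage response, 15 measured, had a median of -0.18 in the MNU parity pair, at percentile 0.51, with Bax at -0.43 and Ogg1, which removes oxidized guanine, at -0.33. Adipocyte genes stood at 0.18 and oxidative phosphorylation genes at 0.15 in parous glands after MNU, at percentiles 99.4 and 99.4, and both lay below 0 as deposited, at -0.18 and -0.35. Fewer than 5 members were measured for B cells, with Ptpn6 at 0.02 and 0.13 in the parity pairs beside Jchain, for brown fat, with Ucp1 at 0.06 and Fabp3 at 0.50 in the untreated parity pair, and for red blood cells, with Alas2 at 0.66 in parous glands after MNU.

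Blank values were not spread at random. Of the brightest 1% of features 14.7%, 9.80%, 42.6% and 42.2% were blank on the parous, virgin, parous MNU and virgin MNU arrays, against 0.961%, 1.01%, 2.25% and 1.52% of the dimmer 90%. The blanks of the untreated parous and virgin arrays overlapped with an odds ratio of 208. Csn2, Glycam1 and Lbp belong to 13 features blank on both parous arrays alone. The opposite pattern, blank on both virgin arrays alone, held 10 features, Pck1 among them. Blanks were more frequent among bright features, with a lowest ratio of 9.70 over the 4 arrays, so the absence of Csn2, Glycam1 and Lbp from the parous comparisons may reflect high rather than low signal. On the untreated virgin array Lbp read 6340 units, above the 99th percentile of 4849. Csn2 and Glycam1 read 1210 and 1280 units, below it, so that ratio says little about them. A fixed brightness limit needs a median fold of 16.1 over the virgin value. For 8 of the 13 features the fold needed exceeds 14.5, the largest in the untreated parity pair. The dimmest would need 113 to 201, which argues against a limit for those. A limit stays open for the others, among them Csn2 at 24.0, Glycam1 at 22.7 and Lbp at 4.59. A flaw over neighbouring positions stays open for the 13 as a set, of which 5 had a blank neighbour in their row on either parous array against 6.15% of other features, but Csn2, Glycam1 and Lbp had none.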
